A study of Homo sapiens with 41 samples.

How the data were processed

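The study measured RNA in 4 human cancer cell lines and mapped RPL22 crosslink sites in 1 of them. RNA-seq libraries numbered 39, in 13 groups of 3, and 2 crosslinking samples of the breast line ZR-75-1 were pooled by the authors into 1 site list. Samples were grouped by their titles and genotype labels. The labels call RPL22-1A1 and RPL22-4A1 knockdowns of RPL22, the series design also names knockouts, and neither says whether the 2 are clones, guides or hairpins, so the word construct and their pooling leave this open. No label says whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

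Each RNA-seq library came as a table of transcripts with an estimated count and a TPM value, deposited as kallisto writes them, per the file headers. The submitters' processing notes name STAR and kallisto with the builds hg19 and GRCh37, without versions or roles. Total RNA was sequenced as paired-end libraries, per the labels' protocols. TPM, which the authors scaled by effective transcript length, entered no test. Every table listed 180253 transcripts, and the totals ran from 9286814 to 31275200 estimated counts per library.

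The crosslink file listed 21-nt windows around deletions, with the deposited count of deletion tags as its score and the number of covering tags in the name. Cells had been irradiated with 400 mJ/cm2 at 254 nm and RPL22 was immunoprecipitated, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, HOMER and bedtools and the build hg38. The site caller is not given in the sources used here. The score equalled the deletion count in the name in all 6820 windows. Pooling leaves no replicate for the sites, and no control immunoprecipitation was used here.

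The reference tables pair gene IDs, not transcript IDs, with symbols, and 0 of the listed transcript IDs were found in them. The planned sums of counts per gene were therefore replaced by the same test on single transcripts, and no transcript is given a gene name. For the same reason the levels of RPL22 and RPL22L1, which would check the labels, MDM4 exon 6 inclusion, transcript usage per gene, tests of gene lists on RNA and the comparison of crosslink sites with RNA changes were not run. Folding of the sites needs a genome sequence and was not run. Effective lengths per library took the place of mean transcript lengths per gene as an offset.

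Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by quasi-likelihood F tests after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 comparisons were RPL22 loss in ZR-75-1 and in NCI-H2110, RPL22 overexpression in LNCaP, RPL22L1 knockdown in LNCaP and RPL22L1 overexpression in CAL851. Where 2 constructs existed, each was a group of its own, and the comparison took the mean of both against the control. Each construct was also compared with the control in 6 further tests and with the other construct in 3. An interaction term compared RPL22 loss between the 2 lines. Each SE of an edgeR log2 fold change was back-calculated as its absolute value divided by the square root of the F statistic. CPM values are rounded estimated counts scaled to the library total, without TMM. Fold changes of the 5 comparisons, which share no control libraries, were set against each other by Spearman correlation across transcripts, which are not independent replicates, and shared calls were set against the product of the call rates. Kallisto's uncertainty in splitting reads between similar transcripts was not used here, and transcripts of 1 gene share reads.

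Except where a later choice is stated, the tests, their samples, the alternatives and the gene lists were fixed before the data were examined. The rule for named genes took those with the largest rise and fall among transcripts past the threshold, with a mean of at least 5 CPM and every perturbed library on the same side of every control library. Because the files do not pair transcripts with genes, it was limited to 2 transcripts per direction. The 4 IDs printed meet the rule in at least 1 comparison, and the choice of these 4 for all comparisons was made after their values were seen.

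Crosslink sites were assigned to the gene spans of RefSeq on GRCh38.p14, the assembly behind hg38, without strand, exons or introns. Shares of sites have exact Clopper-Pearson intervals at 95%, which cover counting error only. Sites with a deletion in at least 90% of covering tags are called high-share sites, and those under 50% low-share sites. For 29 gene lists, the number of members with a site was compared with 10000 random lists matched on gene length in 10 groups, in a two-sided permutation test with Benjamini-Hochberg adjustment. Expression was not matched. The genes named for their many sites and the examples named from each list were picked after their values were seen, and some results are left out of the text because they are withheld for evaluation. This list test on sites was chosen after site counts had been seen, in place of the planned list tests on RNA.

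The edgeR step was tested on simulated counts with 100 transcripts changed 2-fold and 100 changed 4-fold. With dispersions drawn from the trend, 27 and 61 were recovered in the ZR-75-1 design among 54422 transcripts, and 5.4% of 93 calls were false. With dispersions estimated per transcript, 21 and 42 were recovered among 53714, and 25.9% of 85 calls were false. In the LNCaP RPL22 design the trend gave 5 and 37 among 42354 transcripts with 4.5% false calls of 44, and dispersions per transcript gave 5 and 21 among 41936 with 13.3% false calls of 30. The first simulation was made with dispersions per transcript, and the trend was added after its false share had been seen. The list test called 4 of 100 simulated lists without an effect and 91 of 100 with a doubled chance of a site.

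Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, effective lengths as an offset, the replicate number as a block, each library left out, both constructs as 1 group, and all LNCaP libraries in 1 fit. For the position of sites in genes the stricter part of the list by deletion count was used. The same part for the gene lists, and subsets by deletion share or without small RNA genes, were chosen after the data were seen. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.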

Results

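RPL22 is a protein of the large ribosomal subunit and RPL22L1 is its paralog. The series title names RPL22 as a regulator of MDM4 splicing in cancer, and the design sets cell lines with less or more of either protein against controls. RNA was sequenced from ZR-75-1, a luminal breast cancer line, NCI-H2110, a lung cancer line, LNCaP, a prostate cancer line, and CAL851, a breast cancer line. Each of the 13 RNA-seq groups had 3 libraries, with totals from 9286814 to 31275200 estimated counts and from 61566 to 102135 transcripts above 0. RPL22-bound RNA was mapped in ZR-75-1. RNA results are given per transcript, named by ID, because the files do not pair these IDs with genes. A printed transcript may therefore belong to RPL22 or RPL22L1 itself, which was not examined here.

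Loss of RPL22 in ZR-75-1 asked which RNAs change when this protein is reduced. The transcript ENST00000463836 (506 nt) rose from 0.75 ± 0.252 CPM in the GFP control (SD, n = 3) to 36 ± 8.41 with construct RPL22-1A1 and 43.8 ± 6.6 with RPL22-4A1. ENST00000295830 (2190 nt) rose from 0.757 ± 0.38 to 22.8 ± 2.04 and 26.4 ± 3.62 CPM. ENST00000234875 (2078 nt) fell from 560 ± 23.8 to 66.1 ± 3.4 and 154 ± 14.3 CPM, and ENST00000471204 (524 nt) fell from 68.6 ± 12.2 to 12.7 ± 3.21 and 17.2 ± 2.32 CPM. In each of the 4, all 6 perturbed libraries lay on 1 side of all 3 controls.

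The mean log2 fold changes in ZR-75-1 were 5.70 ± 0.32 (SE) for ENST00000463836, 5.00 ± 0.24 for ENST00000295830, -2.49 ± 0.05 for ENST00000234875 and -2.21 ± 0.15 for ENST00000471204. Their adjusted p-values in edgeR's quasi-likelihood test were 0.000495, 0.000194, 2.98e-07 and 0.00151. ENST00000234875 was higher with RPL22-4A1 than with RPL22-1A1, by 1.18 ± 0.07 on the log2 scale (edgeR adjusted p = 0.00229), and in this edgeR fit of 9 libraries it was the only transcript of 58552 called between the constructs. Fitted on their 6 libraries alone edgeR called 4, and DESeq2 called 972 on all 9. In total 10 transcripts rose and 11 fell with RPL22 loss. RPL22-1A1 alone gave 7 higher and 4 lower, and RPL22-4A1 alone gave 11 and 15. DESeq2 called 717 higher and 863 lower on the same counts, including all 21 of edgeR's calls, and leaving out single libraries moved edgeR's counts to between 3 and 10 higher and between 4 and 17 lower. With both constructs treated as 1 group, ENST00000234875 missed the threshold (log2 fold change -2.36, adjusted p = 0.0605 in edgeR, the highest over 15 alternatives).

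**Figure D1:**
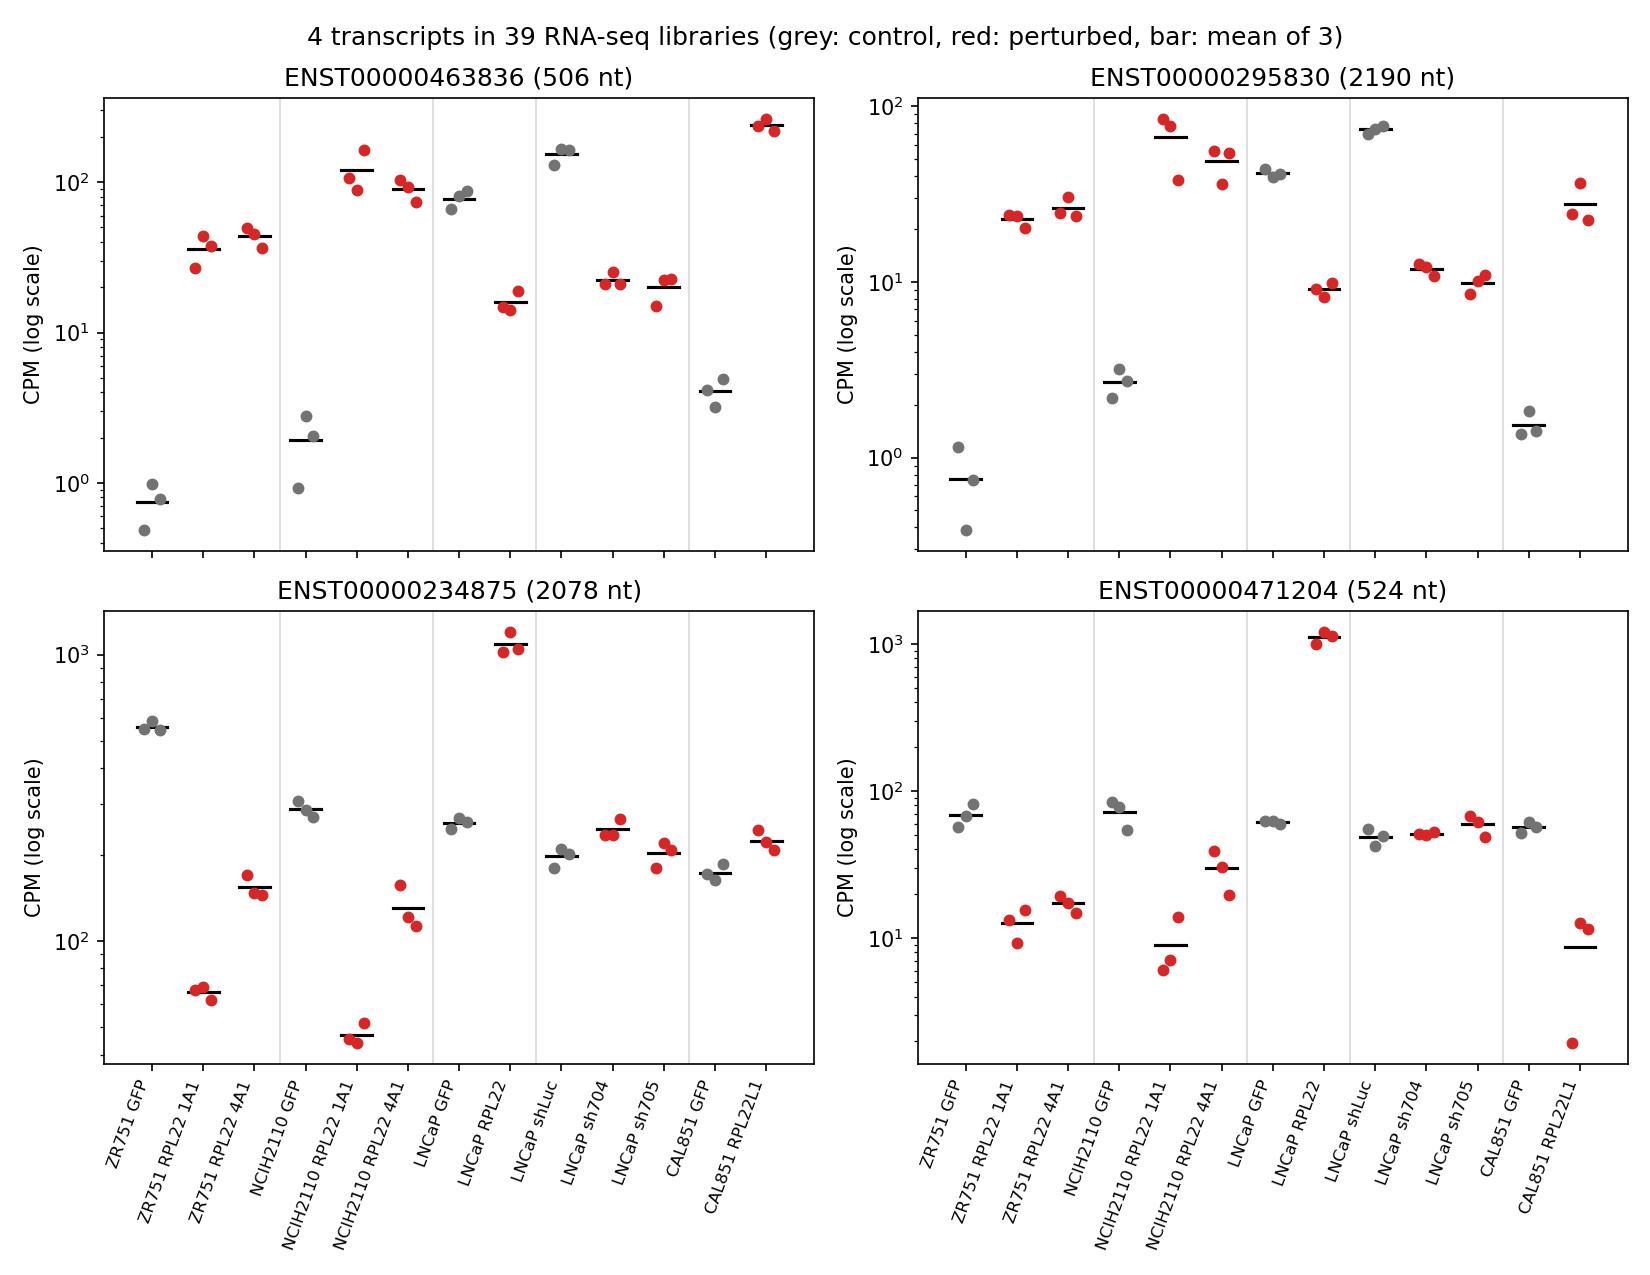
CPM on a log scale of 4 transcripts in the 39 RNA-seq libraries, 3 per group, with controls in grey, perturbed libraries in red and the group mean as a bar. ENST00000463836 and ENST00000295830 lie lowest in the controls of ZR-75-1, NCI-H2110 and CAL851, and ENST00000234875 has a mean of 1092 CPM with RPL22 overexpression in LNCaP.

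RPL22 loss in NCI-H2110 gave the same question in a lung line. ENST00000463836 rose from 1.92 ± 0.944 CPM (SD, n = 3) to 120 ± 39.7 with RPL22-1A1 and 90.4 ± 15.2 with RPL22-4A1, and ENST00000295830 rose from 2.69 ± 0.502 to 66.7 ± 25.2 and 48.6 ± 10.8 CPM. ENST00000234875 fell from 289 ± 18.9 to 46.9 ± 3.98 and 130 ± 23.7 CPM. ENST00000471204 stood at 72.2 ± 15.9 in controls and at 9.01 ± 4.24 and 29.7 ± 9.68 CPM with the constructs, and did not pass the test (log2 fold change -2.13 ± 0.28, edgeR adjusted p = 0.307). In DESeq2 the same transcript was called, with a log2 fold change of -2.10 and an adjusted p of 2.48e-06.

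Log2 fold changes in NCI-H2110 were 5.82 ± 0.37 (SE) for ENST00000463836, 4.45 ± 0.38 for ENST00000295830 and -1.87 ± 0.11 for ENST00000234875, with edgeR adjusted p-values of 0.00201, 0.0172 and 0.00201. Of 58305 transcripts, 3 rose and 2 fell. RPL22-1A1 alone gave 4 higher and 1 lower, RPL22-4A1 alone 1 higher and 0 lower, and the constructs differed in 1. At an unadjusted p under 0.05 the test of RPL22-4A1 had 1905 transcripts, or 3.27%, where no change gives about 5%, and DESeq2 called 130. DESeq2 called 94 higher and 48 lower for both constructs together. Replicate 3 of RPL22-1A1 stood apart from the other NCI-H2110 libraries, with a mean correlation of 0.832 with its line against 0.911 or more for the others, and without it 3 transcripts rose and 1 fell. Without GFP replicate 2 edgeR called 2 in all, and without GFP replicate 3 it called 1. The call of ENST00000295830 was lost without any 1 of the GFP libraries and in 4 other alternatives of 15 (log2 fold changes from 4.29 to 4.59 over all 15, highest adjusted p = 0.242 in edgeR). That of ENST00000463836 was lost without GFP replicate 3 (5.90, edgeR adjusted p = 0.0579) and with the replicate number as a block (5.82, 0.0571). With both constructs as 1 group ENST00000234875 had a log2 fold change of -1.69 and an edgeR adjusted p of 0.911, the highest over its alternatives.

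The lines shared 4 called transcripts. Those higher in both numbered 3, against 0.000576 expected from independent lists among the 46859 tested in both, and those lower in both numbered 1, against 0.000235. ENST00000463836, ENST00000295830 and ENST00000234875 were among them. The remaining shared transcript rose in both lines (log2 fold changes 3.02 and 2.92). It was not called with RPL22 overexpression in LNCaP (0.34, edgeR adjusted p = 0.663), the RPL22L1 knockdown (0.57, 0.109) or RPL22L1 overexpression in CAL851 (0.82, 0.258). Across all 46859 transcripts the fold changes of the lines had a Spearman correlation of -0.018. The interaction test called 2 of 73049 transcripts as differing between lines, and gave adjusted p-values of 1 for ENST00000463836, 1 for ENST00000295830 and 0.37 for ENST00000234875 in edgeR. The differences in log2 fold change, ZR-75-1 minus NCI-H2110, were -0.15 ± 0.66 (SE), 0.52 ± 0.65 and -0.65 ± 0.13 in this order. For ENST00000234875 the unadjusted edgeR interaction p was 0.000141.

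RPL22 overexpression in LNCaP asked for the reverse change. ENST00000234875 rose from 258 ± 12 CPM in the GFP control (SD, n = 3) to 1092 ± 98.4, and ENST00000471204 rose from 61.5 ± 2.05 to 1111 ± 109 CPM. ENST00000463836 fell from 77.9 ± 10.8 to 15.9 ± 2.63 CPM and ENST00000295830 fell from 41.6 ± 2.32 to 9.06 ± 0.859 CPM. These 4 were picked after their values were seen. Another transcript with a larger rise in ZR-75-1 than ENST00000295830 (log2 fold change 5.15) was not called in NCI-H2110 (3.71 ± 0.51, edgeR adjusted p = 0.341), here (-1.19 ± 0.88, 0.662) or with the RPL22L1 knockdown (1.99-fold lower, SE of its log2 0.50, 0.257), and was called with RPL22L1 overexpression in CAL851 (2.85 ± 0.83, 0.0462). For ENST00000234875, ENST00000471204, ENST00000463836 and ENST00000295830 the log2 fold changes were 2.09 ± 0.08 (SE), 4.18 ± 0.10, -2.28 ± 0.15 and -2.19 ± 0.11, with edgeR adjusted p-values of 0.000909, 0.000111, 0.00605 and 0.00247.

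Among 46303 transcripts tested in LNCaP with RPL22 overexpression, 167 rose and 144 fell, of which 30 and 20 changed at least 2-fold. DESeq2 called 1218 higher and 1544 lower, and leaving out any 1 of the 6 libraries left between 7 and 44 higher and between 7 and 35 lower. ENST00000463836 missed the threshold without RPL22 replicate 1 (log2 fold change -2.22, edgeR adjusted p = 0.0598) or 2 (-2.20, 0.0699, the highest p over 12 alternatives). ENST00000295830 missed it with the replicate number as a block (-2.19, edgeR adjusted p = 0.055). Against RPL22 loss in ZR-75-1, 5 transcripts that fell there rose here (0.0397 expected) and 2 that rose there fell here (0.0275 expected), while 0 were called in the same direction. The transcript ENST00000234875 fell in both lines with RPL22 loss and rose here, the only one to do so among 30481 tested in all 5 comparisons.

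RPL22L1 knockdown in LNCaP was made with the hairpins sh704 and sh705 against a luciferase control. ENST00000463836 fell from 154 ± 19.4 CPM (SD, n = 3) to 22.4 ± 2.51 with sh704 and 20.1 ± 4.33 with sh705, and ENST00000295830 fell from 73.9 ± 3.79 to 11.8 ± 0.992 and 9.9 ± 1.24 CPM. Their log2 fold changes were -2.88 ± 0.13 (SE) and -2.80 ± 0.09, with edgeR adjusted p-values of 1.4e-05 and 1.73e-06. Neither differed between hairpins past the threshold (edgeR adjusted p-values 0.292 and 0.0966). ENST00000234875 had a log2 fold change of 0.16 ± 0.08 (edgeR adjusted p = 0.225), but it differed between hairpins by -0.38 ± 0.09 (0.0232), with 0.35 ± 0.09 for sh704 (0.0402) and -0.03 ± 0.09 for sh705 (0.886). ENST00000471204 had a log2 fold change of 0.18 ± 0.13 (0.437).

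Many transcripts differed between the mean of both hairpins and the luciferase control: 2828 of 55616 rose and 3924 fell. The hairpins differed from each other about as widely, with 3529 transcripts higher and 3982 lower with sh705 than with sh704. Alone, sh704 gave 2580 higher and 2675 lower, and sh705 gave 4053 and 4698. With both hairpins as 1 group, 1068 rose and 1541 fell. RPL22 overexpression and RPL22L1 knockdown in LNCaP, which have separate controls, shared 62 higher transcripts (9.64 expected) and 62 lower (11.3 expected), and 38 and 17 moved in opposite directions (13.3 and 8.19 expected).

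RPL22L1 overexpression in CAL851 asked for the reverse of the knockdown. ENST00000463836 rose from 4.09 ± 0.841 CPM (SD, n = 3) to 240 ± 22.7 and ENST00000295830 from 1.54 ± 0.266 to 27.9 ± 7.61 CPM. The fitted change of ENST00000463836 was 64-fold (SE of its log2 0.21) and the log2 fold change of ENST00000295830 was 4.30 ± 0.37, with edgeR adjusted p-values of 0.00017 and 0.00229. ENST00000471204 fell from 56.7 ± 4.76 to 8.68 ± 5.88 CPM (log2 fold change -2.60 ± 0.50, edgeR adjusted p = 0.0146), and ENST00000234875 rose from 173 ± 11.2 to 224 ± 17.3 CPM (0.50 ± 0.13, edgeR adjusted p = 0.0307). Both of these calls were lost when any 1 GFP library was left out, with log2 fold changes of 0.46, 0.44 and 0.54 for ENST00000234875 and -2.69, -2.56 and -2.60 for ENST00000471204. Over 11 alternatives each their adjusted p-values reached 0.134 and 0.0689. ENST00000463836 and ENST00000295830 were the 2 transcripts that fell with the knockdown and rose here and in both lines with RPL22 loss, a set defined after the values were seen. Among the 39046 transcripts tested in both RPL22L1 comparisons, 276 fell with the knockdown and rose here (348 expected) and 344 rose with it and fell here (292 expected), while 777 fell in both (418 expected) and 315 rose in both (243 expected).

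In CAL851, 5542 of 48247 transcripts rose and 5957 fell. The RPL22L1 libraries held 71725, 80303 and 61566 transcripts above 0 at totals of 18148925, 17605541 and 15534417 estimated counts, where the GFP libraries held 90628, 89148 and 89329 at 17501661, 16206880 and 16996723. The 10 most abundant transcripts took 11.19%, 8.38% and 8.5% of the counts in the RPL22L1 libraries and 5.69%, 5.71% and 5.72% in the GFP libraries. The count of changed transcripts fell to 725 higher and 562 lower without GFP replicate 1, to 838 and 611 without GFP replicate 2, to 2330 and 1774 without GFP replicate 3, and to 3186 and 3150 without RPL22L1 replicate 1. With no filter on low counts 2382 rose and 2648 fell.

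**Figure D2:**
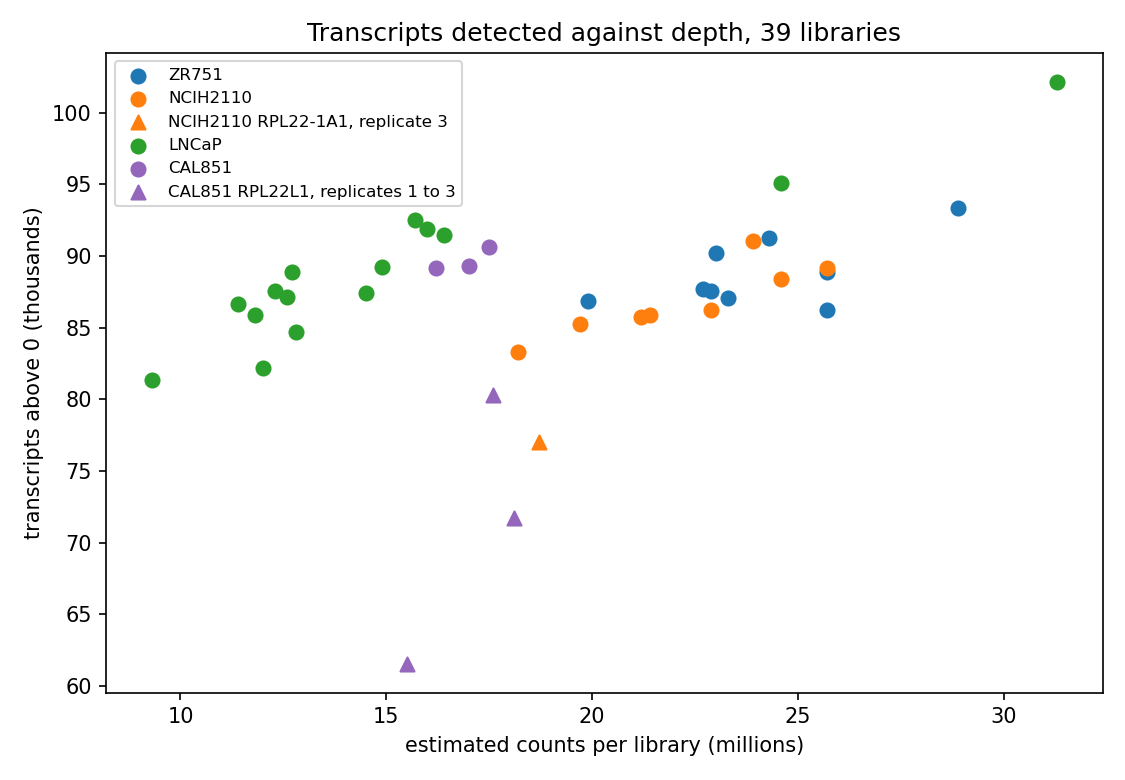
Transcripts above 0 against total estimated counts in 39 libraries, coloured by cell line. The 3 RPL22L1 libraries of CAL851 and replicate 3 of RPL22-1A1 in NCI-H2110, drawn as triangles, hold between 61566 and 80303 transcripts, fewer than any other library.

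RPL22 crosslink sites in ZR-75-1 were read from deletions at 6820 windows on hg38. A site lay in the span of TRPS1, a transcription factor gene of luminal breast cells, 31 times. GSE1 held 15 sites, BRINP3 13 and UBAP2L 5. MDM4, which encodes an inhibitor of p53, held 1 site, on chromosome 1 at 204556788 to 204556808 on the plus strand, with a deletion in 10 of 35 tags (28.6%). RPL22 and RPL22L1 held 0 sites, in a list that names only called sites.

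The gene spans held 6198 of the 6820 sites (90.9%, 95% interval 90.2 to 91.6), 5578 of them in the 3648 protein-coding genes with a site and 748 in lncRNA genes. Protein-coding genes with a site had a median span of 64.8 kb, against 19.3 kb for those without. In the mitochondrial rRNA gene RNR2 a site centred at position 2863 had 524 of 2111 tags. The 909 of 1597 tags centred at position 3107 of RNR2 lie on a placeholder base of the reference that human mitochondrial DNA lacks, so a deletion there needs no crosslink. RNU5E-1, a spliceosomal RNA gene on chromosome 1, had 301 of 1769 tags centred at 11908240, and the site at 49280390 on chromosome 20, in SNORD12B and ZFAS1, had 266 of 346. In genes with at least 2 sites in no other span, 955 of 1047 had all of them on 1 strand. Whether a site is exonic or intronic was not analysed here.

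Deletions were found in at least 90% of the covering tags at 5709 sites (83.7%, 95% interval 82.8 to 84.6), and in under 50% at 680 (10.0%, 9.3 to 10.7). The mitochondrial sites differed: 120 of 141 (85.1%, 78.1 to 90.5) were low-share sites, against 560 of 6679 nuclear sites (8.4%, 7.7 to 9.1). Coverage differed too: 103 of the mitochondrial and 83 of the nuclear sites had over 300 tags, and of these 99.0% and 97.6% were low-share. Small RNA genes held 115 sites, 74 of them low-share. The MDM4 site was low-share, and the UBAP2L sites had deletions in 20 of 20, 37 of 38, 38 of 38, 22 of 22 and 2 of 3 tags. Whether a higher share marks a stronger crosslink was not tested, and the reason for the many high-share sites stays open.

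**Figure D3:**
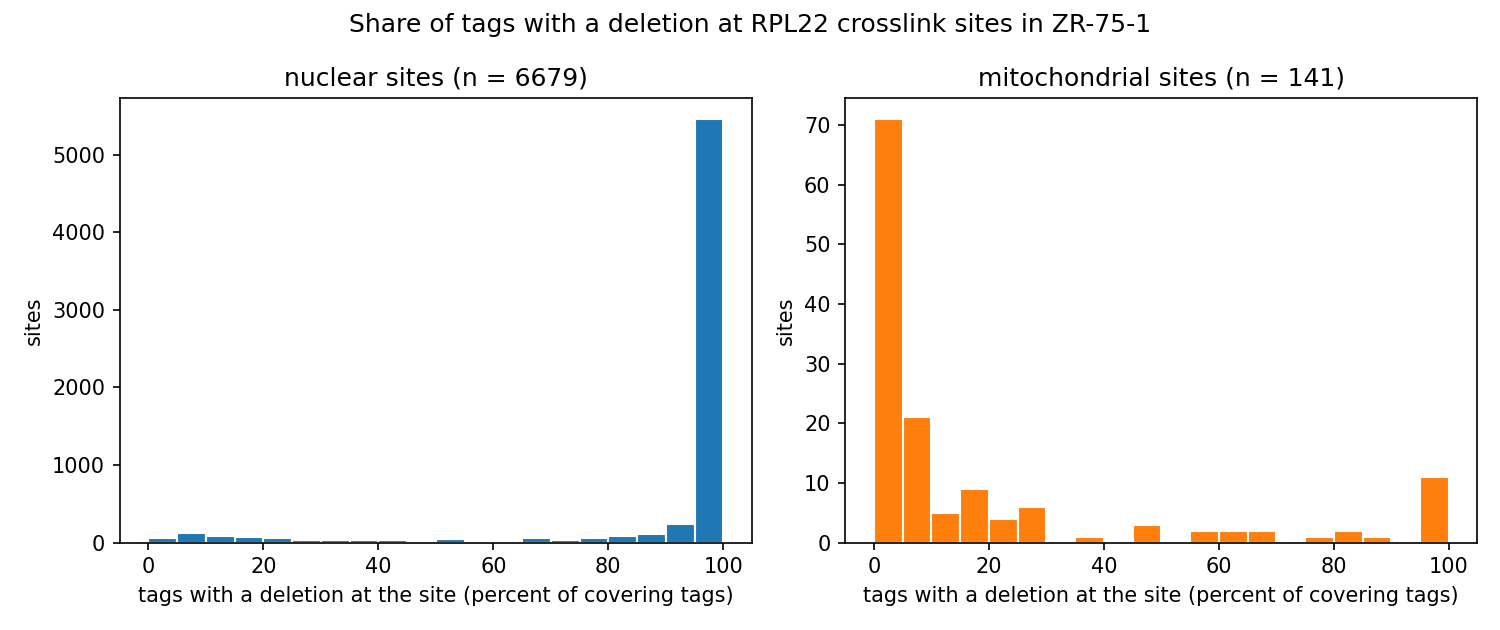
Number of sites by the percent of covering tags with a deletion, for 6679 nuclear and 141 mitochondrial sites. Nuclear sites pile up near 100%, and 120 of the mitochondrial sites lie under 50%.

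Several gene lists, among them those of translation and splicing, held sites more often than genes of like length, without matching on expression. Ribosomal protein genes with a site numbered 34 of 78 (5.17 expected), among them RPL5, RPL10 and RPS3. Translation factor genes numbered 16 of 30 (4.18 expected), with EEF2 and EIF4G1, and snoRNA host genes 9 of 17 (0.25 expected), with GAS5 and SNHG1. Without sites in small RNA genes the snoRNA host genes fell to 4 of 17 (0.24 expected), and GAS5 and SNHG1 were no longer among them. Splicing regulator genes numbered 18 of 37 (6.13 expected), with SRSF1, HNRNPK and PTBP1. Luminal breast marker genes numbered 9 of 14 (2.13 expected), with ESR1 at 7 sites and GATA3 at 2, and hypoxia and glycolysis genes 14 of 26 (4.55 expected), with GAPDH and LDHA. Each of these 6 lists had a permutation p of 0.0002, the smallest these draws give, and an adjusted p of 0.000967.

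Estrogen response genes held sites in 14 of 30 (5.71 expected, permutation adjusted p = 0.00249), with GREB1 and PGR, and oxidative phosphorylation genes in 10 of 29 (3.15, 0.00507), with ATP5F1A. Epithelial junction genes held them in 9 of 22 (3.45, 0.0161), with CDH1, endoplasmic reticulum chaperone genes in 7 of 20 (2.63, 0.0496), with HSPA5, and TGF-beta and SMAD genes in 10 of 21 (4.78, 0.0496), with SMAD3. On the stricter sites by deletion count the calls of epithelial junction genes (permutation adjusted p = 0.0638) and TGF-beta and SMAD genes (0.592) were lost, and on high-share sites those of the same lists (0.112 and 0.0916) and of oxidative phosphorylation genes (0.0748). On low-share sites these 3 lists and those of chaperones and of hypoxia and glycolysis were lost, with adjusted p-values from 0.0555 to 1. The other 18 of the 29 lists did not pass the threshold. Among them p53 targets held sites in 7 of 34 genes (5.21 expected, adjusted p = 0.724), including MDM2 and CDKN1A, interferon response genes in 1 of 30 (4.1, 0.309) and leukocyte markers in 0 of 12 (1.21, 0.724). Prostate luminal markers held sites in 0 of 11 genes (2.04, 0.365). Random lists were not matched on expression.

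**Figure D4:**
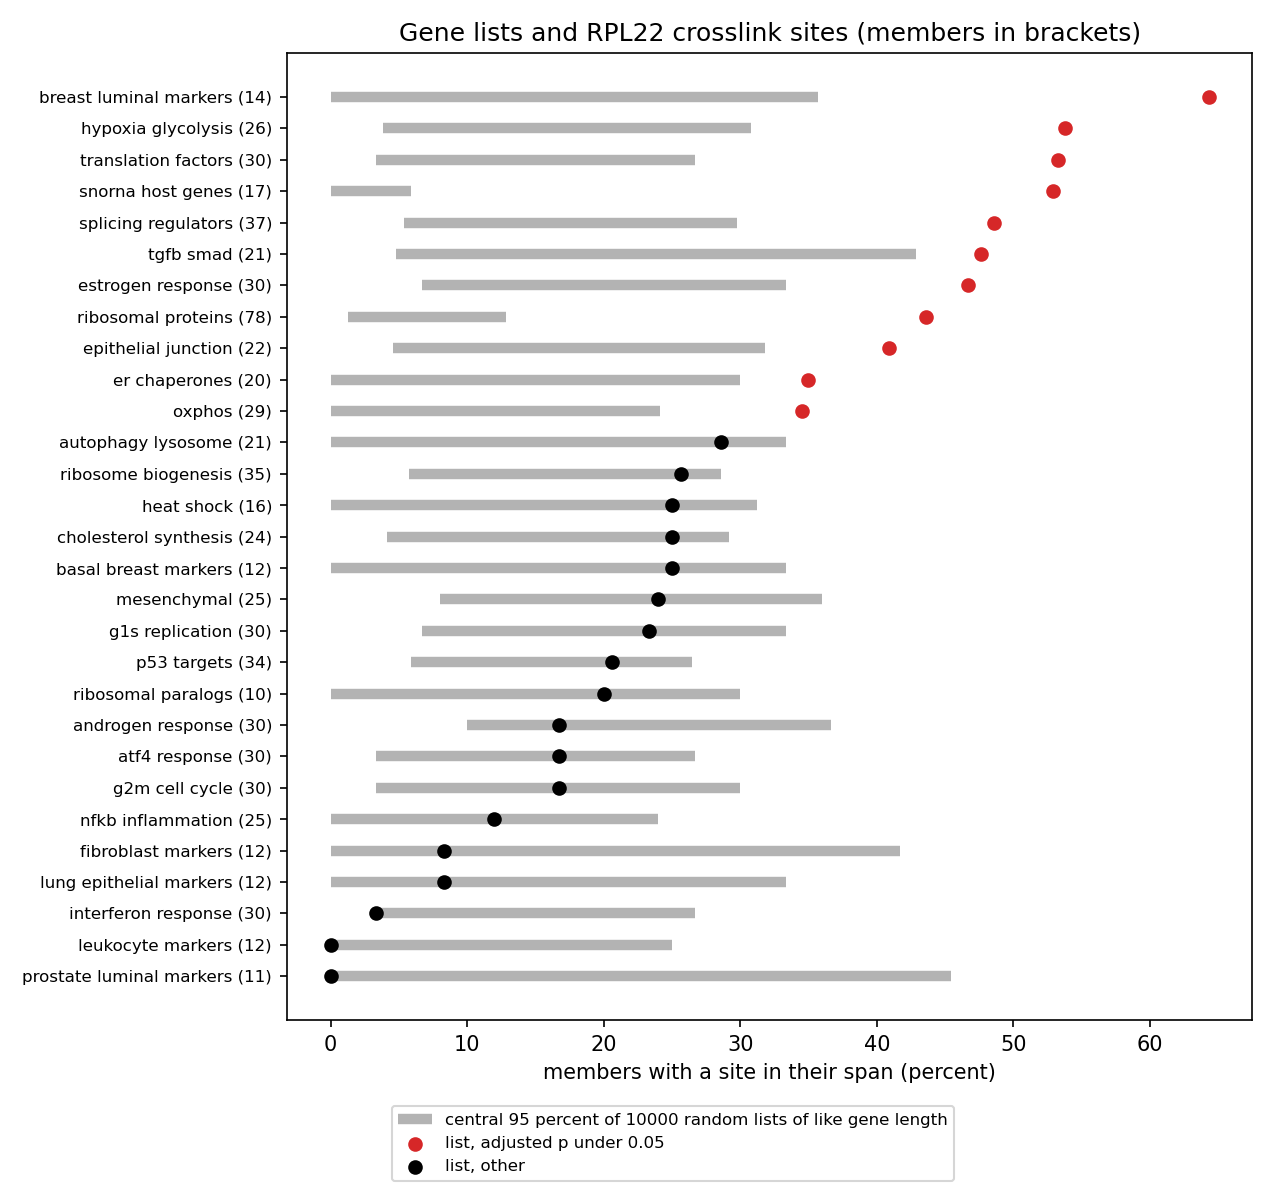
Percent of the members of 29 gene lists with an RPL22 crosslink site (points, with list size in brackets) beside the central 95% of 10000 random lists of like gene length (grey bars). The 11 lists in red, led by luminal breast markers at 64.3%, passed an adjusted p of 0.05.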

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

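The test for a difference between lines was chosen with the other tests, and the levels of its 2 transcripts were looked at only after the result was seen.

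RPL22 loss had a different effect in ZR-75-1 than in NCI-H2110 for 2 of 73049 transcripts, by the interaction term in edgeR. For 1 the difference in log2 fold change was 8.55 ± 0.89 (SE), with an adjusted p of 0.0418. Its levels were 102 ± 3.88 CPM in ZR-75-1 controls (SD, n = 3) and 134 ± 13.1 and 143 ± 7.78 with RPL22-1A1 and RPL22-4A1. In NCI-H2110 they were 1.51 ± 0.855 in controls and 0 in all libraries of both constructs. The fitted difference is therefore no bound, and its SE is no measure of precision. By edgeR this transcript was called in neither line alone (adjusted p = 0.0921 in ZR-75-1). For the other the difference was 5.23 ± 0.74 (interaction adjusted p = 0.0418), with 0.132 ± 0.229 rising to 4.97 ± 1.01 and 3.75 ± 0.747 CPM in ZR-75-1 beside 9.73 ± 1.61, 6.93 ± 1.44 and 9.6 ± 2.42 in NCI-H2110. At an unadjusted p under 0.05 the test had 4385 transcripts.

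Chance cannot be excluded for these 2: of 50 splits of the libraries within each line, 6 gave at least 2 transcripts, the real split included, and the highest other gave 6. DESeq2 called 672 transcripts. With DESeq2's size factors in edgeR and without any 1 of 15 of the 18 libraries edgeR called 0, and without the other 3 it called 1 (NCI-H2110 GFP replicate 2), 4 (RPL22-1A1 replicate 2) and 3 (RPL22-1A1 replicate 3). No other explanation was tested.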

How the results depend on the processing

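Alternatives chosen only after the results were seen are those without the NCI-H2110 library that stands apart in the correlation with CAL851, and those on low-share sites, high-share sites, sites outside small RNA genes and the stricter sites for gene lists. Of 276 values of named transcripts under alternatives, 250 kept direction and side of the threshold, 25 missed it, 1 passed it anew and 0 reversed. Leave-one-out fits aside, 44 of 91 counts stayed within 1.5 times and 47 did not. Of 21 correlations 17 moved by no more than 0.05, a limit set after the data were seen, and of 116 list results 106 were the same and 10 weaker. Unless stated, the cause was not tested. Alternatives for gene sums, transcript usage, MDM4 exon 6, RPL22L1 and UBAP2L transcripts, gene lists on RNA, sites against RNA changes and folding were not run, since the files do not pair transcripts with genes and no genome was used. How depth limits the calls was not tested.

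DESeq2 called more. RPL22 loss in ZR-75-1 gave 717 higher and 863 lower, with 1010 changed for RPL22-1A1, 1881 for RPL22-4A1 and 972 between them. RPL22 loss in NCI-H2110 gave 94 higher and 48 lower, with 230, 130 and 178. RPL22 overexpression in LNCaP gave 1218 higher and 1544 lower, the RPL22L1 knockdown 4900 higher and sh704 8680 changed, and the interaction 672. All 21 edgeR calls in ZR-75-1 and all 5 in NCI-H2110 were among DESeq2's, with 299 of 311, 6560 of 6752 and 10844 of 11499 for RPL22 overexpression, RPL22L1 knockdown and CAL851. With DESeq2's size factors in edgeR the interaction called 0, where DESeq2 called 672 and edgeR with TMM had 4385 at an unadjusted p under 0.05.

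Without the filter more transcripts are tested. RPL22-4A1 then changed 11 in ZR-75-1 and 2 in NCI-H2110, where 1 was lower with RPL22 loss and 2 differed between constructs. The RPL22L1 knockdown had 2477 lower, sh704 3195 changed, sh705 5800 and sh705 against sh704 4747, and CAL851 had 2382 higher and 2648 lower. With both constructs as 1 group, ZR-75-1 had 5 higher and 3 lower, NCI-H2110 1 lower and the RPL22L1 knockdown 1068 higher and 1541 lower. In 1 fit of 15 LNCaP libraries, RPL22 overexpression had 340 higher and 373 lower.

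Replicate numbers do not pair the libraries in the labels. Libraries correlating best with their own number were 3 of 9 in ZR-75-1, 5 of 9 in NCI-H2110, 4 of 6 with RPL22 overexpression, 5 of 9 with the RPL22L1 knockdown and 2 of 6 in CAL851, a hint from the data and not the design. With the replicate number as a block, ZR-75-1 had 5 higher and 4 lower, with 7 changed for RPL22-1A1 and 6 for RPL22-4A1. NCI-H2110 had 0 higher and 1 lower, with 2 changed for RPL22-1A1, 0 for RPL22-4A1 and 0 between them by edgeR. Without the block edgeR had 2475 transcripts at an unadjusted p under 0.05 for both constructs (4.24%) and 1905 for RPL22-4A1 (3.27%), where no change gives about 5%, and DESeq2 called 94 higher, 130 and 178. LNCaP RPL22 overexpression had 3 higher and 10 lower, CAL851 1629 higher and 969 lower, and the interaction 0 with the block within each line. The block ended the calls of ENST00000463836 (5.82, adjusted p = 0.0571) and ENST00000295830 (4.43, 0.153) in NCI-H2110, of ENST00000295830 with RPL22 overexpression (-2.19, 0.055), and of ENST00000234875 (0.50, 0.0951) and ENST00000471204 (-2.77, 0.0514) in CAL851, and no other call of these 4.

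Each library was left out in turn. For ZR-75-1 these were 3 to 10 higher and 4 to 17 lower: 3 and 5 without GFP replicate 1, 4 and 4 without GFP 2, 4 and 5 without GFP 3, 7 and 6 without RPL22-1A1 1, 6 and 8 without 1A1 2, 7 and 6 without 1A1 3, 10 and 17 without RPL22-4A1 1, 4 and 4 without 4A1 2, and 5 and 6 without 4A1 3. For NCI-H2110 they were 0 to 3 higher and 1 to 2 lower: 1 and 1 without GFP 2, 0 and 1 without GFP 3, 3 and 1 without 1A1 1, 2 and 1 without 1A1 2, 3 and 1 without 1A1 3, 3 and 1 without 4A1 2, and 2 and 1 without 4A1 3. DESeq2 on all 9 libraries called 94 higher, and edgeR had 2475 at an unadjusted p under 0.05.

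For RPL22 overexpression in LNCaP the ranges were 7 to 44 higher and 7 to 35 lower: 44 and 35 without GFP 1, 18 and 18 without GFP 2, 36 and 30 without GFP 3, 9 and 11 without RPL22 1, 7 and 7 without RPL22 2, and 21 and 15 without RPL22 3. For the RPL22L1 knockdown they were 1538 to 2475 higher and 2408 to 3419 lower, with 1641 higher without shLuc 1, 1538 and 2455 without shLuc 2, and 2408 lower without shLuc 3. For CAL851 they were 725 to 5940 higher and 562 to 6539 lower: 725 and 562 without GFP 1, 838 and 611 without GFP 2, 2330 and 1774 without GFP 3, and 3186 and 3150 without RPL22L1 1. The interaction gave 0 to 4: 4 without NCI-H2110 1A1 2, 3 without 1A1 3, 1 without NCI-H2110 GFP 2, and 0 by edgeR without any other, where all libraries had 4385 at an unadjusted p under 0.05 and DESeq2 called 672.

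At 5 CPM or more in both comparisons the Spearman correlations were -0.086 for ZR-75-1 and NCI-H2110, -0.11 for ZR-75-1 and CAL851, and 0.283 for NCI-H2110 and CAL851. Over all transcripts tested in both, that of NCI-H2110 and CAL851 was 0.149, and -0.035 without replicate 3 of RPL22-1A1. Sites in protein-coding spans were 83.3% of the stricter sites and 63.1% of low-share sites, lncRNA genes held 17.2% and small RNA genes 10.9% of low-share sites, and no span held 7.0% of the stricter and 6.2% of low-share sites. Lists past the threshold were 9 for the stricter sites, 6 for low-share sites, 8 for high-share sites and 11 without small RNA genes, against 11.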

Other observations

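Tests chosen only after the results were seen are those on depth, on other lines and on wrong labels, those on deletion shares and those on transcripts that follow a label.

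RPL22 crosslink sites in ZR-75-1 also lay in genes of small RNAs. Of the 6820 sites, 47 were in 40 snoRNA genes, 27 in 19 tRNA genes and 13 in 7 snRNA genes, which serve RNA modification, translation and splicing. The median share of covering tags with a deletion was 0.6 in snoRNA genes, 0.172 in tRNA genes and 0.085 in snRNA genes, against 1 in protein-coding genes. These medians were not matched on coverage, and high-share sites were rarer at high coverage. The tRNA genes include mitochondrial ones, such as TRNE and TRNM.

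A hypothesis formed from these data is that transcripts follow the labelled direction of RPL22L1 in both comparisons that carry its label. Those that fell with RPL22L1 knockdown and rose with RPL22L1 overexpression were 252 of 30481, where independent calls give 292, so this direction had no excess. Of the 39046 transcripts tested in both, 344 rose with the knockdown and fell with overexpression (292 expected), and calls in the same direction were 777 lower (418 expected) and 315 higher (243 expected).

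The CAL851 RPL22L1 libraries stood apart from the GFP libraries in 11499 transcripts and held fewer transcripts above 0. Depth is argued against, since after thinning to the smallest total the highest RPL22L1 library still held 0.899 of the lowest GFP library, and so is RNA of another line of the study. Of transcripts at 20 CPM or more in another line's controls and at 0 in CAL851 GFP, at most 23.8% were above 0 in any RPL22L1 library. The highest correlation with another line's control mean was lower than in GFP (difference -0.086). This cannot decide, since the RPL22L1 libraries also correlated less within their own group. RPL22L1 replicate 2 had a correlation of 0.66 with the NCI-H2110 library described next, above 0.648, the highest of the GFP libraries with any library of another line. Independent random loss of molecules beside a shared difference stays open. Fold changes against different GFP libraries correlated at 0.528 or more, but a shared difference gives this with or without such loss. Mean correlations within the group were 0.874, 0.88 and 0.849 for the RPL22L1 libraries, against 0.953, 0.951 and 0.947 for GFP. An effect of RPL22L1 and a technical difference shared by the 3 libraries stay open.

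Replicate 3 of RPL22-1A1 in NCI-H2110 stood apart from its line. Depth is argued against by a gap of 0.114 in mean correlation after thinning. A library of another NCI-H2110 group under this label stays open. It lay nearer to the other RPL22-1A1 libraries than to GFP at 2 of 2 transcripts. This cannot decide, since the rule that named them had used this library, and the other construct was not compared. A library of another line is argued against by the correlation of replicate 3 with NCI-H2110 controls, 0.853, above that with any other line. A technical signature shared with the CAL851 RPL22L1 libraries may be present: its deviation correlated at 0.496 with the CAL851 fold changes over 14201 transcripts, where 30 libraries of other groups gave -0.306 to 0.247. The CAL851 GFP libraries, which enter those fold changes and are not among the 30, gave -0.162, -0.254 and 0.307. The correlation of fold changes between NCI-H2110 RPL22 loss and CAL851 was 0.242 with this library and -0.038 without it, over 14400 transcripts. Part of the CAL851 change may thus be technical, which no test here separates from an effect of RPL22L1.

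Most crosslink sites carry the deletion in nearly all covering tags. The share of nuclear sites that do so fell with coverage, from 92.4% at 2 to 10 tags through 89.1%, 83.8% and 51.7% to 0 of 83 sites over 300 tags, and low coverage stays open, since the 41.4% of 411 sites with at least 100 tags lies between the shares that would settle it. A fault of sequencing or alignment that marks all tags alike stays open too, since at over 100 and up to 300 tags 13.3% of 15 mitochondrial sites (95% interval 1.7 to 40.5) and 51.7% of 323 nuclear sites did so, too few to settle it. Also open are bases missing from the ZR-75-1 genome, with 1.7% of 6679 nuclear sites at shares of 40% to 60% and no genome of the line used here. Whether runs of A in the genome matter, given the tailing and oligo(dT) steps in the labels' protocols, was not tested, nor was a biological explanation.

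Other splits of the libraries tested chance. For RPL22 loss in both lines and the RPL22L1 knockdown, 100 of the possible splits were used, and only the real split gave its count. The counts were 21 for RPL22 loss in ZR-75-1 (highest other 10), 5 in NCI-H2110 (highest other 4) and 6752 for the knockdown (highest other 5332). This argues against chance but does not exclude it, since not all splits were drawn and they mix constructs that may differ. In NCI-H2110 the margin was narrow. Which libraries the split with 5332 calls in the knockdown put together was not examined, and sh704 and sh705 also differ from each other. For comparisons of 6 libraries the 10 splits are too few for a share under 0.05. The real value and the highest other were 11499 and 0 for CAL851, 311 and 3 for RPL22 overexpression in LNCaP, 10 and 1 for RPL22-1A1 and 14 and 1 for RPL22-4A1 in ZR-75-1, and 4 and 3 between them. They were 4 and 2, 3 and 1, and 0 and 1 for the same tests in NCI-H2110, and 4827 and 2 for sh704, 7489 and 2 for sh705, and 6383 and 2 between the hairpins. The 0 calls by edgeR, which 10 of the 10 splits matched or passed, came from the 6 construct libraries fitted alone, and with all 9 libraries edgeR called 1 and DESeq2 178.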
